A study of Mus musculus with 12 samples.

How the data were processed

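Hepatocytes of 12 mice were profiled by poly(A) RNA sequencing, 3 mice for each of 4 groups. Per the labels' protocols, C57BL/6J mice aged 3 months on a chow diet were injected through the tail vein with AAV8-TBG-eGFP or AAV8-TBG-eGFP-P16, 70% partial hepatectomy followed after 1 week, and primary hepatocytes were isolated by collagenase perfusion before the operation (0 h) or 48 h after it. Per the labels' protocols, viability and purity of the cells were at least 95%. The sex of the mice is not given in the sources used here. Groups were taken from the labels, and every library belonged to one of them.

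The deposited table holds whole-number counts of reads per gene for each library, not normalized by the authors. Per the submitters' processing notes, the tools were Trim Galore, STAR 2.5.0c, SAMtools, Picard and HTSeq, and the genome build was mm10. The tools' settings, the annotation release and the strand setting are not given in the sources used here. Counts of a gene with an antisense or overlapping neighbour may therefore lack reads set aside as ambiguous, or hold reads of that neighbour. This concerns Slc25a25 (Naif1), Rgs16 (Gm28513), Ucp2 (Dnajb13), Etfb (Gm45233), Prtn3 (Plppr3), Cdkn1a (AC167363.2), Ddit3 (Mars), Manf (Rbm15b and Dcaf1), Fgg (Gm30097), Ccnd1 (LTO1), Foxm1 (Tex52), Casp9 (Cela2a), Grn (Fam171a2), Csad (Zfp740), Elovl3 (Pitx3), Apoa4 (Gm10680), Junb (Prdx2), Kif20a (Cdc23), Rps28 (Kank3), Slc13a2 (Slc13a2os), Acsl1 (Gm45244), Top2a (Gm23451), Glb1 (Tmppe), Hmgb1 (Uspl1), Klkb1 (Gm45753), Pdia4 (Mir704), Cd74 (Mir5107), Bcl3 (Gm16175), Atxn2 (Sh2b3), Dbp (Sphk2), Nr1d1 (Thra), Usp2 (Gm39325), Arntl (Gm45355) and Xist (Tsix), whose values are uncertain to that extent. The Mup, Saa, Cyp4a12 and ribosomal protein families have near-identical copies or pseudogenes, and their single members are uncertain too.

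The table had 31053 gene rows, of which 30934 Ensembl identifiers were found in the GENCODE vM21 annotation of GRCm38 (the assembly of mm10), which gave the positions. Of the deposited symbols 27 had become dates and 173 were missing, and all were restored from the Ensembl identifiers. Rows that shared a symbol with another row (122) were kept apart by identifier. Rows that name no gene stayed out of library sizes and tests: reads in no annotated feature were 3.62 to 9.8% of a library's total and ambiguous reads 4.87 to 8.8%. At 48 h the former were 3.62 to 3.92% in GFP and 4.39 to 9.8% in P16 libraries. Whether this bears on the comparison of the arms was not tested. A repeat of the same numbers in the deposited workbook was not used. Reads in genes came to 14617049 to 25409451 per library, and 11051 to 12404 genes had at least 10 reads. Replicates were separate mice with a correlation of log CPM between 0.950 and 0.981, and no pair of libraries of a group was as close as counting noise (lowest chi-square per degree of freedom 14.6).

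Tests were run in R 4.3.3. The main test was the quasi-likelihood F test of edgeR 4.0.16 with robust dispersions, on all 12 libraries in a model of 4 group means, after TMM scaling (factors 0.825 to 1.23) and the filterByExpr filter, which left 12257 genes. P values were adjusted by Benjamini-Hochberg over all genes tested, and a gene passed at an adjusted p under 0.05. The contrasts were P16 against GFP at 0 h and at 48 h, 48 h against 0 h in GFP and in P16 mice, and the interaction. The median SE of a log2 fold change was about 0.2, or 0.287 for the interaction. Of 40 gene lists, the 36 with at least 5 tested members were tested in each contrast by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, and by camera with an estimated correlation and by fry. With the estimated correlation the lists that passed were mitosis, replication and repair genes after hepatectomy in both arms and male-biased genes in P16 mice, and none between the arms or in the interaction. List members were also adjusted over the list alone. List scores are the mean log2 CPM of the members in a library less the mean of GFP mice at 0 h, with a prior count of 0.5.

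Genes named in the text followed a rule: Cdkn2a, then Thbd, F2r, Cdkn1a, Cdkn2b, Glb1, Lmnb1, Hmgb1 and Mki67 in every comparison; the 5 largest rises and 5 largest falls among genes past the test with a mean of at least 5 CPM over the libraries compared and no overlap between groups (overlap was allowed in the interaction); and up to 4 members of a list with the largest changes past the test, or the 2 with the lowest p where none passed. Unnamed gene models were skipped, except Gm379 in the interaction. Not every value under the rule is printed: Glb1 and Hmgb1, for example, are given only between the arms at 0 h and in the interaction. Clock genes, sex-linked genes, all 12 genes of the interaction and single library values of Saa1 were chosen after their values were seen. Cdkn2b had at most 14 reads in any library and was removed by the filter.

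A group with 0 reads of a gene was given a floor of 3 counts per library, 0.0961 to 0.238 CPM, and the fold is then a lower bound. Where a group held 1 to 3 reads, the ratio has a 95% interval. Intervals and floors cover counting error only. The design, lists, naming rule and alternatives were set before the data were examined, except where a later choice is stated. The alternatives were other scalings (RLE, upper quartile), no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, replicate number as a block, an adjusted p under 0.01, an added log2 change of at least 1, the 6 libraries of a comparison alone, and each library left out in turn. Single genes and lists were not run under all of these: single genes had no upper-quartile, 1 CPM, 6-library or stricter threshold setting (13 alternatives, 19 in the interaction), and lists had the 1 CPM filter but neither DESeq2 nor limma-voom nor upper-quartile scaling (12, or 18 in the interaction). Offsets for transcript length and GC content, and leaving out GFP replicate 2 at 0 h together with P16 replicate 2 at 48 h, were chosen after seeing the data.

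The scripts were tested on simulated data drawn from the real means and library sizes. For the comparison at 0 h (12066 genes), edgeR recovered 14.0% of 1.5-fold, 52.8% of 2-fold and 91.5% of 4-fold changes with 7 false calls among 118. For the comparison at 48 h (12044 genes) it recovered 14.7%, 65.6% and 89.1% with 4 false calls among 112. With no simulated effect, edgeR called 0 genes and camera 0 lists at either time. Genes were simulated independently of one another, so this result does not test camera where genes of a list move together. A simulated length trend that gave 873 calls at 48 h gave 0 after the offsets (12060 genes).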

Results

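Poly(A) RNA was sequenced from hepatocytes freshly isolated from 12 mice, in 4 groups of 3 mice. All mice had received an adeno-associated virus, AAV8, in which the hepatocyte-active TBG promoter drove either eGFP alone (GFP mice) or eGFP together with P16 (P16 mice). P16 is the cyclin-dependent kinase inhibitor encoded by Cdkn2a, and it accumulates in senescent cells. In each arm, cells were taken before surgery (0 h) or 48 h after removal of 70% of the liver, an operation after which the remaining hepatocytes re-enter the cell cycle. The libraries held 14617049 to 25409451 reads in genes. After low counts were removed, 12257 genes were tested. The principal component that separated the times held 59.2% of the variance, and the next held 8.38%. Levels below are library-size-scaled counts (CPM) as mean ± SD over the 3 mice of a group. Changes are log2 fold changes with a Benjamini-Hochberg adjusted p from the edgeR quasi-likelihood test. Their standard error (SE) is the size of the change divided by the square root of that test's F statistic. A gene said to differ in 3 of 3 mice had no overlap between the groups, which chance gives in 10% of cases.

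Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653, minus strand, GRCm38) is the gene that the P16 vector carries. Its reads can show the P16 vector in a library, but their absence does not show the eGFP vector. Cdkn2a had 620, 105 and 355 reads in the P16 libraries at 0 h and 256, 425 and 402 in those at 48 h. The GFP libraries had 0 reads in all 3 mice at 0 h, and 0, 5 and 0 reads at 48 h. Reads of the delivered P16 and of the mouse gene were counted together and were not separated. At 48 h Cdkn2a rose from 0.0836 ± 0.145 to 19.3 ± 6.71 CPM, 251-fold (log2 fold change 7.97, SE 1.30, adjusted p = 0.0385). At 0 h it stood at 26.9 ± 21.5 CPM in P16 mice, at least 131-fold above a floor of 3 counts per library in GFP mice and higher in 3 of 3, yet the spread between 6.38 and 49.2 CPM left the adjusted p at 0.0914. Without replicate 2 of the P16 mice at 0 h that value was 0.00901, and it ranged from 1.83e-07 to 0.223 over the alternatives. The call at 48 h was lost without replicate 1, 2 or 3 of the GFP mice and without replicate 2 or 3 of the P16 mice (adjusted p from 8.87e-06 to 0.178 over the alternatives). Within the P16 arm Cdkn2a did not differ between the times (log2 fold change -0.48, SE 0.72, adjusted p = 0.645).

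The title of the series names thrombomodulin and its partner receptor PAR1, so Thbd (ENSMUSG00000074743, chromosome 2, 148404466 to 148408188, minus strand) and F2r (ENSMUSG00000048376, chromosome 13, 95601803 to 95618487, minus strand) were followed in every comparison. Thbd, a thrombin-binding membrane protein, rose after hepatectomy in P16 mice from 0.375 ± 0.333 to 4.33 ± 1.56 CPM, 10.9-fold and in 3 of 3 mice (log2 fold change 3.45, SE 0.63, adjusted p = 0.000349). This call held under all 13 alternatives. In GFP mice Thbd was 1.54 ± 0.881 CPM at 0 h and 3.01 ± 0.863 CPM at 48 h (log2 fold change 0.94, SE 0.53, adjusted p = 0.189). The test of the difference between these responses did not pass (2.51, SE 0.83, adjusted p = 0.221, range 0.0543 to 0.517 over the alternatives). Between the arms Thbd passed at neither time (log2 fold change -1.99, adjusted p = 0.208 at 0 h, and 0.52, adjusted p = 0.653 at 48 h). F2r, the thrombin receptor PAR1, fell after hepatectomy in P16 mice from 24.0 ± 11 to 12.3 ± 3.75 CPM (log2 fold change -0.97, SE 0.28, adjusted p = 0.0154). That call was lost without P16 replicate 2 at 0 h (adjusted p = 0.0665, range 0.00203 to 0.0665). It was 28.9 ± 3.87 and 24.1 ± 0.642 CPM in GFP mice at the 2 times (adjusted p = 0.502), and its interaction did not pass (-0.70, SE 0.39, adjusted p = 0.519). At 48 h F2r was lower in P16 than in GFP mice in 3 of 3, without passing the test (log2 fold change -0.96, SE 0.28, adjusted p = 0.0871).

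**Figure D1:**
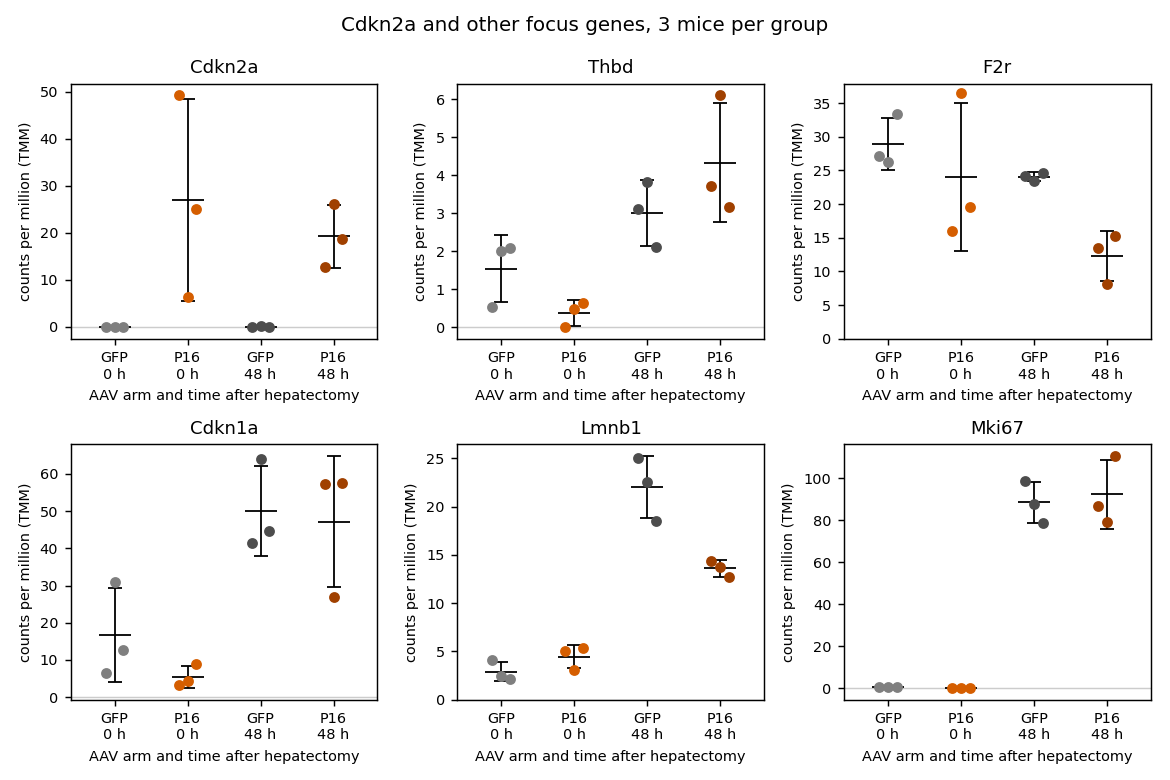
Expression of Cdkn2a, Thbd, F2r, Cdkn1a, Lmnb1 and Mki67 in CPM (vertical axis of each panel) in GFP and P16 mice at 0 h and 48 h after hepatectomy (horizontal axis), with each point a mouse and bars for the mean and SD of 3. Cdkn2a is at or near 0 in GFP mice and between 6.38 and 49.2 CPM in P16 mice, and Mki67 is at 88.6 ± 9.92 and 92.4 ± 16.3 CPM in GFP and P16 mice at 48 h.

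The comparison of P16 with GFP mice at 0 h asks which transcripts of the resting liver differ with the P16 vector. A clock gene score, given under other observations, was 0.99 higher in P16 mice at 0 h (SE 0.733). A difference in time of day or feeding between the arms is therefore not excluded for the genes below. Slc25a25 (chromosome 2, 32414487 to 32451445), a mitochondrial carrier of adenine nucleotides, fell from 297 ± 32.6 to 104 ± 13.9 CPM (log2 fold change -1.51, SE 0.15, adjusted p = 7.92e-05). Rgs16, which shortens G protein signalling, rose 13.5-fold from 1.19 ± 1.07 to 16 ± 5.0 CPM (log2 fold change 3.76, SE 0.51, adjusted p = 0.00729). Gdf15, a stress-induced cytokine, rose 3.75-fold to 139 ± 35.2 CPM (adjusted p = 0.0358), and Hes1, a target of Notch signalling, rose 3.02-fold to 20.3 ± 7.82 CPM (adjusted p = 0.0311). Got1, the cytosolic aspartate aminotransferase, fell 1.92-fold from 259 ± 13.1 to 135 ± 14.3 CPM (adjusted p = 0.0159). Among the other large changes, Arrdc3 rose 6.45-fold (adjusted p = 0.0305) and Etfb rose 3.25-fold (adjusted p = 0.0298), while Ucp2 fell 2.46-fold (adjusted p = 0.0273) and Zfp385a fell 1.94-fold (adjusted p = 0.0349). Each of these genes differed in 3 of 3 mice, which the naming rule required of the largest changes. In all, 27 genes passed, 15 higher and 12 lower, against 1652 at an unadjusted p under 0.05; DESeq2 called 214 and limma-voom 19. Of the other focus genes, Cdkn1a (log2 fold change -1.62, SE 0.63, adjusted p = 0.322), Lmnb1 (0.62, SE 0.26, adjusted p = 0.307), Glb1 (-0.31, SE 0.20, adjusted p = 0.528) and Hmgb1 (0.21, SE 0.12, adjusted p = 0.462) did not pass. The count of 27 became 148 without GFP replicate 1, 12 without GFP replicate 3, 47 without P16 replicate 2 and 5 without P16 replicate 3. Of 13 genes that passed here and were followed through the alternatives, Slc25a25 alone kept its call under all 13 alternatives run for single genes (adjusted p 1.6e-17 to 0.0022). Rgs16 lost it with 2 libraries left out (range 7.09e-12 to 0.0595), and the other 11 lost it without P16 replicate 3, with Got1 then at 0.0973. With limma-voom Etfb, Hes1, Ucp2 and Zfp385a lost it as well, and with the length and GC offsets Gdf15, Hes1 and Zfp385a.

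Among markers of other liver cells, the macrophage and endothelial lists were called lower in P16 mice at 0 h with the preset correlation and not with an estimated one. The score changed by -0.127 (SE 0.336) for stellate and by 0.0304 (SE 0.322) for cholangiocyte markers. Of 21 markers of Kupffer cells and other macrophages, 2 fell over all genes tested, Cd74 (3.00-fold, from 16.8 ± 7.28 to 5.58 ± 1.81 CPM, adjusted p = 0.0305), the MHC class II invariant chain, and Slc40a1 (1.89-fold, adjusted p = 0.0358), the iron exporter ferroportin. DESeq2 called 8 of the 21 and limma-voom 0, with 19 at an unadjusted p under 0.05. Adjusted over the list alone, 17 were lower, with a list median of -1.67. The list was called by camera with a preset correlation (adjusted p = 2.04e-16) and not with an estimated one (adjusted p = 0.706 with an estimated correlation). Of 19 sinusoidal endothelial markers 0 passed the edgeR test, 0 adjusted over the list alone, with 9 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Together the 19 had a median of -0.64 (adjusted p = 2.12e-07, and adjusted p = 0.827 with an estimated correlation). Cdh5, an endothelial cadherin, stood at a log2 fold change of -1.15 (adjusted p = 0.198). Of 28 acute phase genes, whose products the liver secretes in inflammation, 0 passed over all genes in edgeR or limma-voom, 5 in DESeq2 and 10 at an unadjusted p under 0.05, and 1 was lower adjusted over the list alone. Together the 28 had a median of -0.50 (adjusted p = 2.42e-05, and adjusted p = 0.827 with an estimated correlation). These groups moved with a library that stood apart: GFP replicate 2 held 6413 CPM of the acute phase gene Saa1, against 71.6 and 445 CPM in the other GFP mice and 33.8 to 99.1 CPM in P16 mice. Its macrophage marker score was 1.08, against -1.06 and -0.0190 in the other GFP mice and -1.75 to -1.23 in P16 mice. Without it the medians were -0.72 for macrophage, -0.34 for endothelial and -0.14 for acute phase genes. With GFP replicate 1 left out instead, they were larger, at -2.04 for macrophage and -0.66 for acute phase genes. Cd74 lost its call with limma-voom, without GFP replicate 3 and without P16 replicate 1 or 3, with adjusted p from 4.01e-05 to 0.142 over the alternatives. Slc40a1 lost its call with limma-voom, with the length and GC offsets, without GFP replicate 2 and without P16 replicate 2 or 3, and its adjusted p ranged from 1.13e-04 to 0.139.

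Cell cycle genes were sparsely expressed at 0 h. Of 44 mitosis genes 1 fell, Top2a, a DNA topoisomerase of dividing cells, from 0.705 to 0.0265 CPM (ratio 0.0344, 95% counting interval 8.44e-04 to 0.207, adjusted p = 0.0311), and 8 were lower and 2 higher adjusted over the list alone. The mitosis list had a median of -0.55, or -0.45 with genes near zero counts set at their bounds (adjusted p = 0.00728, and adjusted p = 0.827 with an estimated correlation). Without GFP replicate 2 that median was -0.31, and with P16 replicate 2 at 48 h left out as well the call was lost (adjusted p = 0.0579, the highest over the alternatives). Mki67, the proliferation marker, was 0.449 ± 0.0736 CPM in GFP and 0.0939 ± 0.0423 CPM in P16 mice, lower in 3 of 3 without passing (log2 fold change -2.19, SE 0.54, adjusted p = 0.116). A further 3 lists were called higher, with 0 members past the edgeR or limma-voom test over all genes. They were 25 immediate early genes (median 0.70, 12 higher and 2 lower adjusted over the list alone, adjusted p = 0.00915). The others were 80 ribosomal protein genes (0.27, 10 higher adjusted over the list alone, adjusted p = 5.43e-13) and 73 nuclear genes of oxidative phosphorylation (0.29, 0 adjusted over the list alone, adjusted p = 1.31e-12). All 3 had adjusted p = 0.827 with an estimated correlation, and at an unadjusted p under 0.05 they had 15, 30 and 27 members, of which DESeq2 called 5, 6 and 0. Junb, an immediate early transcription factor, was 120 CPM in GFP and 308 CPM in P16 mice (log2 fold change 1.36, SE 0.37, adjusted p = 0.189). The immediate early score stood apart in P16 replicate 1, at 1.06, against -0.0493 and 0.192 in the other P16 mice and -0.0511 to 0.063 in GFP mice. Without that library the list median was 0.42 and the call was lost, as it was without GFP replicate 1 (adjusted p = 0.127, the highest over the alternatives). The ribosomal protein and oxidative phosphorylation medians were 0.16 and 0.12 with GFP replicate 2 and P16 replicate 2 at 48 h both left out. Top2a lost its call with limma-voom, which called 0 of the 44 against 6 by DESeq2 and 15 at an unadjusted p under 0.05, and without GFP replicate 3 or any P16 replicate (adjusted p 4.62e-05 to 0.230 over the alternatives). Among 19 p53 target genes Gdf15 alone passed, 1 adjusted over the list alone (list median -0.20, adjusted p = 0.860). It was also the single gene past the test among 23 genes of the senescence-associated secretory phenotype, with 1 higher and 1 lower adjusted over the list alone (median -0.19, adjusted p = 0.143).

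The comparison of P16 with GFP mice at 48 h asks how the vector changes the regenerating liver. Sdf2l1 (chromosome 16, 17130138 to 17132383), an endoplasmic reticulum chaperone component, rose 3.00-fold from 26.7 ± 5.23 to 80.4 ± 20.6 CPM (log2 fold change 1.59, SE 0.21, adjusted p = 0.00662). Fgb, the fibrinogen beta chain, rose 2.72-fold from 2950 ± 245 to 8036 ± 3493 CPM (log2 fold change 1.45, SE 0.22, adjusted p = 0.00662). Tcp11l2 (chromosome 10, 84576626 to 84614359) fell 2.97-fold from 13.2 ± 2.75 to 4.43 ± 0.164 CPM (log2 fold change -1.57, SE 0.21, adjusted p = 0.00570). Ccnd1, the cyclin D1 gene whose product partners with the kinases that P16 inhibits, fell 1.88-fold from 55.1 ± 7.62 to 29.2 ± 4.70 CPM (log2 fold change -0.91, SE 0.19, adjusted p = 0.0223). Mki67 did not differ (log2 fold change 0.06, SE 0.13, adjusted p = 0.866). After Cdkn2a, the largest rises were Prtn3 (10.2-fold, adjusted p = 0.0317), Efna1 (3.68-fold, adjusted p = 0.0493), Lrg1 (3.14-fold, adjusted p = 0.0385) and Tspyl2 (3.07-fold, adjusted p = 0.0360). The largest falls besides Tcp11l2 were Cyp8b1, the sterol 12-hydroxylase of bile acid synthesis (4.48-fold, adjusted p = 0.0412), Rnf125 (3.13-fold, adjusted p = 0.0163), Crebrf (2.5-fold, adjusted p = 0.0247) and Apoa4 (2.48-fold, adjusted p = 0.0469). Each gene named here as changed at 48 h differed in 3 of 3 mice, again required of the largest changes. In all, 280 genes passed, 152 higher and 128 lower, against 2142 at an unadjusted p under 0.05; DESeq2 called 707 and limma-voom 972. The count fell to 31, 28 and 10 without GFP replicate 1, 2 and 3, and was 21 without P16 replicate 2 and 175 without P16 replicate 3. Tcp11l2, Sdf2l1 and Mup1 kept their calls under all 13 alternatives. Fgb lost its call without GFP replicate 3 alone (adjusted p 1.24e-07 to 0.0507 over the alternatives), and Ccnd1 lost its call without any 1 GFP library or P16 replicate 2 or 3 (1.48e-04 to 0.138).

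Lists of secretory and stress genes were called higher in P16 mice at 48 h with the preset correlation and not with an estimated one. Of 25 genes of the endoplasmic reticulum stress response 8 rose, 13 adjusted over the list alone, and none fell. Together the 25 had a median of 0.64 (adjusted p = 3.49e-13, and adjusted p = 0.335 with an estimated correlation). Among them were Sdf2l1, Ddit3 (2.61-fold, adjusted p = 0.0317), a stress transcription factor, Manf (2.11-fold, adjusted p = 0.0306), and the disulfide isomerase Pdia4 (1.90-fold, from 159 ± 14.8 to 302 ± 37.0 CPM, adjusted p = 0.00662). Of 28 acute phase genes 10 rose, 18 adjusted over the list alone, and none fell. Together the 28 had a median of 1.05 (adjusted p = 5.88e-17, and adjusted p = 0.335 with an estimated correlation). They included Fgb, Fgg (2.72-fold, adjusted p = 0.00662), Fga (2.36-fold, adjusted p = 0.0116) and the lipopolysaccharide-binding protein Lbp (2.44-fold, adjusted p = 0.0373). Of 20 coagulation genes 5 rose, 7 adjusted over the list alone, among them the fibrinogen genes and Kng1 (1.81-fold, adjusted p = 0.0217), with a median of 0.30 (adjusted p = 8.63e-08, and adjusted p = 0.335 with an estimated correlation). The acute phase score was 1.46 in P16 replicate 2, which stood apart from 0.709 and 0.345 in the other P16 mice and from -0.129 to 0.0237 in GFP mice, and the acute phase median was 0.65 without that library. The coagulation median was 0.19 with P16 replicate 2 and GFP replicate 2 at 0 h both left out. Macrophage markers had a median of -0.08 at 48 h with 0 of 21 past the edgeR test, 0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom (list adjusted p = 0.537). Of 23 genes of the senescence-associated secretory phenotype 0 passed over all genes in edgeR, and 1 was higher adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 1 in DESeq2 and in limma-voom. Together the 23 had a median of 0.35 (adjusted p = 0.0262, and adjusted p = 0.335 with an estimated correlation). The list lost its call without GFP replicate 3 (adjusted p = 0.0575) and without P16 replicate 2. Cxcl1, a chemokine of that list, was 12.5 CPM in GFP and 107 CPM in P16 mice and just missed the test (adjusted p = 0.0522). Pdia4 and Fgg lost their calls without GFP replicate 3 alone (highest adjusted p = 0.0507), and Fga without GFP replicate 2 or 3 or P16 replicate 2. Ddit3 and Manf lost their calls with the length and GC offsets, and so did Lbp, also with no filter. Ddit3 also lost its call without any 1 GFP library or P16 replicate 2 or 3 (adjusted p 8.19e-04 to 0.168), and Manf without any 1 GFP library or P16 replicate 2 (3.44e-04 to 0.172). Lbp and Kng1 lost theirs without GFP replicate 3 and P16 replicate 2 among others.

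Of 80 ribosomal protein genes 18 rose at 48 h in P16 mice, 57 adjusted over the list alone, and none fell. Together the 80 had a median of 0.46 (adjusted p = 1.18e-27, and adjusted p = 0.335 with an estimated correlation). Rps21 rose 1.85-fold from 182 ± 8.33 to 336 ± 68.3 CPM (adjusted p = 0.00949). Rpl38, Rpl41 and Rps28 had log2 fold changes of 0.86, 0.80 and 0.77 (adjusted p = 0.0258, 0.0362 and 0.0270). Single ribosomal protein genes share sequence with many pseudogenes and are uncertain one by one. Of 73 nuclear genes of oxidative phosphorylation 4 rose, and 34 were higher and 2 lower adjusted over the list alone. Together the 73 had a median of 0.38, or 0.24 with length and GC offsets (adjusted p = 1.22e-11, and adjusted p = 0.575 with an estimated correlation). Of 12 mitochondrially encoded transcripts 0 passed the edgeR test over all genes, 5 did by DESeq2, 4 by limma-voom and 10 at an unadjusted p under 0.05, and 10 were higher adjusted over the list alone. Together the 12 had a median of 0.75 (adjusted p = 2.20e-07, and adjusted p = 0.425 with an estimated correlation). Of 12 genes with male-biased expression in liver 1 fell, 7 adjusted over the list alone. Together the 12 had a median of -0.56 (adjusted p = 1.45e-06, and adjusted p = 0.335 with an estimated correlation). That gene was the major urinary protein gene Mup1, from 9.85 ± 0.841 to 4.03 ± 0.438 CPM (2.45-fold lower, adjusted p = 0.00662), a family of near-identical copies whose reads are uncertain. Ribosomal protein transcripts were highest in P16 replicate 2 (score 1.12, against 0.690 and 0.817 in the other P16 mice and 0.342 to 0.504 in GFP mice), and the list median was 0.33 without it. Rps21 lost its call without GFP replicate 2 or 3 and without P16 replicate 2 (adjusted p 9.6e-06 to 0.0747 over the alternatives), and the other 3 ribosomal protein genes lost theirs without GFP replicate 3 or P16 replicate 2.

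Of 13 genes with female-biased expression in liver 4 were tested, too few for a list test. At 0 h 1 of the 4 rose in P16 mice, 2 adjusted over the list alone (median 2.30). This was the cytochrome P450 gene Cyp2c69, which has close copies and is uncertain, from 0.972 ± 0.321 to 6.16 ± 2.27 CPM (log2 fold change 2.64, SE 0.43, adjusted p = 0.0159). Its call was lost without GFP replicate 3 and without P16 replicate 3 (adjusted p 8.67e-07 to 0.0973 over the alternatives). At 48 h 0 of the 4 passed in edgeR or limma-voom, 2 did in DESeq2 and 2 at an unadjusted p under 0.05, and 2 were higher adjusted over the list alone (median 1.61). The score of the 4 genes was 1.20 to 1.86 in P16 and -0.155 to 0.267 in GFP mice at 0 h, and 2.15 to 3.41 against 1.51 to 1.71 at 48 h, where chance separates 3 from 3 mice in 10% of cases. All 12 libraries held reads of the Y-linked gene Ddx3y, 686 to 1370, and at most 3 reads of Xist, the transcript of the inactive X chromosome.

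The cell cycle lists were not called between the arms at 48 h. In the edgeR test over all genes 0 of 44 mitosis genes (median -0.04, adjusted p = 0.448), 0 of 40 replication genes (0.01, adjusted p = 0.908) and 0 of 22 DNA repair genes (-0.07, adjusted p = 0.493) passed, and 0 of each did so adjusted over the list alone. At an unadjusted p under 0.05 there were 5, 1 and 0, DESeq2 called 1, 0 and 0, and limma-voom called 7, 0 and 0. Kif20a, a kinesin of cell division, had a log2 fold change of -0.98 (adjusted p = 0.0871). Lmnb1, the lamin B1 gene that is often low in senescent cells, was 22.0 ± 3.25 CPM in GFP and 13.6 ± 0.869 CPM in P16 mice. It was lower in 3 of 3, as chance gives in 10% of cases, without passing the test (log2 fold change -0.70, SE 0.22, adjusted p = 0.0882). Cdkn1a was 50.001 ± 12.1 and 47.2 ± 17.6 CPM (log2 fold change -0.08, SE 0.55, adjusted p = 0.966). Of 19 p53 target genes 0 passed in edgeR, 3 at an unadjusted p under 0.05, 0 in DESeq2 and 1 in limma-voom (median -0.29, adjusted p = 0.155). Of 6 genes of thrombin receptors and their partners 0 passed in edgeR, 1 in DESeq2 and 2 in limma-voom, with 2 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone (median -0.22, adjusted p = 0.371). Several metabolic and signalling lists were not called but had members past the test. Of 14 NF-kappaB target genes 2 rose, 3 adjusted over the list alone (median 0.23, adjusted p = 0.0697), with 3 called by DESeq2 and 3 by limma-voom. They were Nfkbiz (2.62-fold, adjusted p = 0.0426) and Bcl3 (1.70-fold, adjusted p = 0.0360). Both calls were lost without any 1 GFP library or P16 replicate 2 or 3 (adjusted p 0.00256 to 0.204 and 0.00104 to 0.235 over the alternatives). The score of the list was 0.234 to 0.715 in P16 and 0.0417 to 0.115 in GFP mice. Lpin1 (2.36-fold, adjusted p = 0.0316) and Fads2 (1.67-fold, adjusted p = 0.0228) fell among 19 lipogenic genes (3 lower adjusted over the list alone). So did the fatty acid regulator Ppara (1.73-fold, adjusted p = 0.0373) among 29 fatty acid oxidation genes (2 lower adjusted over the list alone), and Ajuba (2.04-fold, adjusted p = 0.00803) among 9 YAP target genes (3 lower adjusted over the list alone). These 4 genes that fell lost their calls without P16 replicate 2 and without GFP replicate 2, and all but Ajuba also without GFP replicate 3 and P16 replicate 3. Ppara lost its call with the length and GC offsets and without any single library of the comparison (adjusted p 0.00212 to 0.202 over the alternatives), and the highest adjusted p was 0.183 for Lpin1, 0.130 for Fads2 and 0.0563 for Ajuba.

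**Figure D2:**
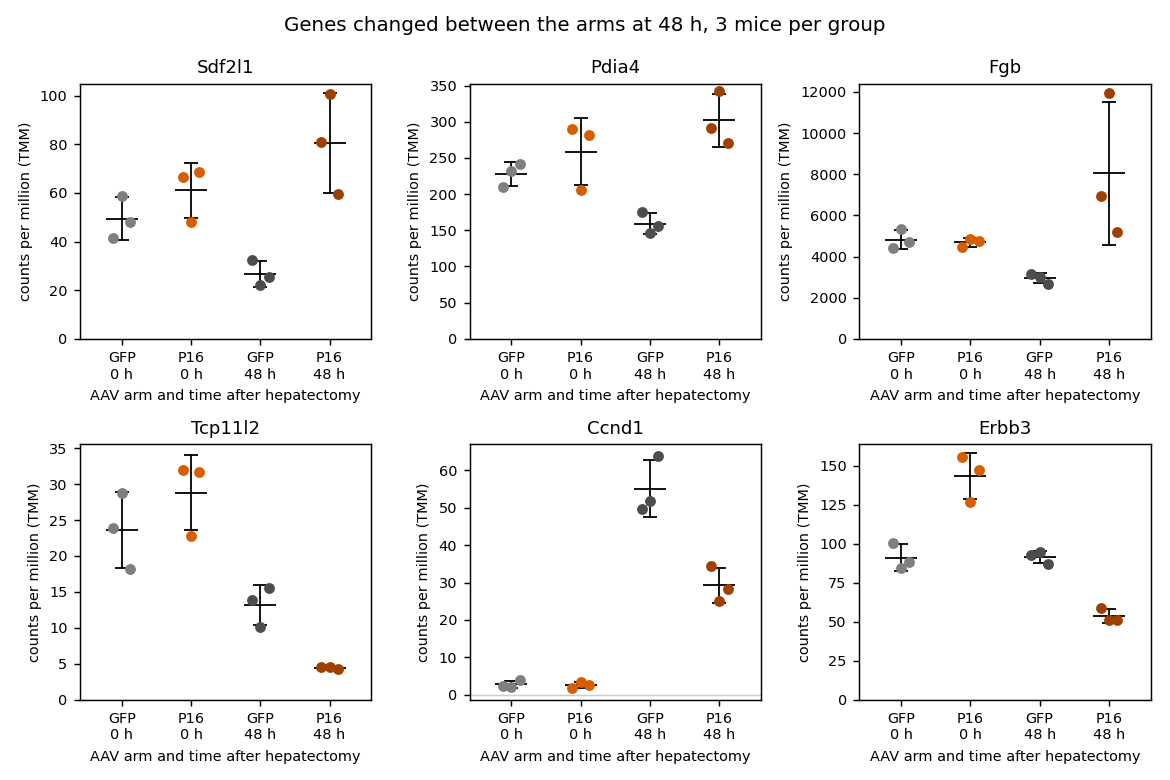
Expression of Sdf2l1, Pdia4, Fgb, Tcp11l2, Ccnd1 and Erbb3 in CPM (vertical axis of each panel) in GFP and P16 mice at 0 h and 48 h after hepatectomy (horizontal axis), with each point a mouse and bars for the mean and SD of 3. At 48 h Sdf2l1 is at 26.7 ± 5.23 CPM in GFP and 80.4 ± 20.6 CPM in P16 mice, and Erbb3 lies above GFP at 0 h and below it at 48 h.

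The comparison of 48 h with 0 h in GFP mice describes the response to hepatectomy without P16. A clock gene score, given under other observations, also differed between the times without overlap, in GFP and in P16 mice. Surgery was therefore not separated from any difference in time of day or feeding. No group was operated on without resection, so resection was not separated from the operation itself either. Cell division genes led the response: all 44 mitosis genes rose, 44 adjusted over the list alone. Together the 44 had a median of 6.72, or 6.68 with genes near zero counts at their bounds (adjusted p = 2.21e-184, and adjusted p = 0.000312 with an estimated correlation). Foxm1, a transcription factor of the division programme, rose at least 125-fold, from 0 reads in 3 of 3 mice to 25.8 ± 1.22 CPM (adjusted p = 3.27e-08), and Dlgap5 at least 113-fold (adjusted p = 2.44e-10). Mki67 rose 194-fold (log2 fold change 7.60, SE 0.22, adjusted p = 2.94e-14), Ccnd1 from 2.79 to 55.1 CPM (log2 fold change 4.32, SE 0.23, adjusted p = 1.24e-10) and Lmnb1 7.64-fold (2.93, SE 0.25, adjusted p = 4.23e-08). Of 40 replication genes 37 rose and 1 fell, 38 and 1 adjusted over the list alone, among them the helicase subunit Mcm5 (46.2-fold) and the ribonucleotide reductase subunit Rrm2 (24.4-fold). Together the 40 had a median of 2.47 (adjusted p = 2.10e-41, and adjusted p = 0.00869 with an estimated correlation). Of 22 DNA repair genes 17 rose and none fell, 17 adjusted over the list alone. Together the 22 had a median of 2.32 (adjusted p = 3.76e-14, and adjusted p = 0.00869 with an estimated correlation). In all, 4117 genes passed, 2111 higher and 2006 lower, 33.6% of those tested. Cyp8b1 fell 20.5-fold from 523 ± 119 to 25.3 ± 16.3 CPM (adjusted p = 6.22e-05). The fatty acid elongase Elovl3 fell 16.9-fold (adjusted p = 3.77e-05), Csad 15.3-fold (adjusted p = 4.39e-04) and Gadd45g 9.64-fold (adjusted p = 0.0245). Gadd45g lost its call without GFP replicate 1 at 0 h or any GFP library at 48 h (highest adjusted p = 0.0879).

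Among lists of liver metabolism, those of glucose, urea cycle and amino acid, fatty acid oxidation, bile acid and oxidative phosphorylation genes were called lower in GFP mice after hepatectomy. Lipid synthesis and drug metabolism lists were not called. Of 19 lipogenic genes 6 rose and 3 fell, 7 and 3 adjusted over the list alone (median 0.39, adjusted p = 0.492). Of 31 drug metabolism genes 7 rose and 14 fell, 9 and 14 adjusted over the list alone (median -0.27, adjusted p = 0.136). Of 25 cholesterol synthesis genes 2 rose and 1 fell, 2 and 1 adjusted over the list alone (median 0.01, adjusted p = 0.840). Of 18 glucose metabolism genes 13 fell and none rose, 14 lower adjusted over the list alone. Together the 18 had a median of -1.03 (adjusted p = 1.34e-05, and adjusted p = 0.0553 with an estimated correlation). G6pc, the glucose-6-phosphatase of glucose output, fell 8.38-fold (log2 fold change -3.07, SE 0.19, adjusted p = 8.67e-10). Of 26 urea cycle and amino acid genes 19 fell and 2 rose, 20 and 2 adjusted over the list alone, including Hal (3.72-fold) and Tdo2 (3.51-fold). Together the 26 had a median of -0.68 (adjusted p = 6.18e-07, and adjusted p = 0.340 with an estimated correlation). Of 29 fatty acid oxidation genes 13 fell and 1 rose, 14 and 1 adjusted over the list alone. Together the 29 had a median of -0.53 (adjusted p = 3.66e-04, and adjusted p = 0.192 with an estimated correlation). Of 21 bile acid genes 12 fell and 1 rose, 12 and 2 adjusted over the list alone, with Cyp8b1 among those that fell. Together the 21 had a median of -0.57 (adjusted p = 5.89e-05, and adjusted p = 0.220 with an estimated correlation). Of 73 nuclear genes of oxidative phosphorylation 29 fell and 1 rose, 29 and 1 adjusted over the list alone. Together the 73 had a median of -0.26, or -0.15 without GFP replicate 1 at 0 h and -0.42 with GFP replicate 2 at 0 h and P16 replicate 2 at 48 h both left out (adjusted p = 0.00108, and adjusted p = 0.769 with an estimated correlation). Of 20 coagulation genes 16 fell and 1 rose, 18 and 1 adjusted over the list alone, including the prekallikrein gene Klkb1 (3.81-fold). Together the 20 had a median of -0.68 (adjusted p = 2.23e-05, and adjusted p = 0.344 with an estimated correlation). Of 12 male-biased genes 11 fell, 11 adjusted over the list alone, including Hsd3b5 (8.0-fold). Together the 12 had a median of -1.71 (adjusted p = 3.91e-11, and adjusted p = 0.0553 with an estimated correlation). All 12 mitochondrially encoded transcripts fell, 12 adjusted over the list alone. Together the 12 had a median of -1.65 (adjusted p = 6.23e-08, and adjusted p = 0.340 with an estimated correlation). The share of reads from the mitochondrial genome moved with them, at 14.5 to 21.4% at 0 h and 7.77 to 9.95% at 48 h. Of 19 p53 target genes 11 rose and 2 fell, 12 and 3 adjusted over the list alone, including Phlda3 (20.7-fold). Together the 19 had a median of 1.11 (adjusted p = 1.15e-04, and adjusted p = 0.112 with an estimated correlation). Cdkn1a itself did not pass (1.56, SE 0.57, adjusted p = 0.0693, and 3.53e-04 to 0.184 over the alternatives).

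The same comparison in P16 mice asks how the response runs where the vector supplies P16. All 44 mitosis genes rose here too, 44 adjusted over the list alone. Together the 44 had a median of 6.91, or 6.57 with bounds (adjusted p = 3.29e-163, and adjusted p = 0.000960 with an estimated correlation). Mki67 rose by a log2 fold change of 9.86 (SE 0.27, adjusted p = 1.11e-14), Aurkb at least 103-fold (adjusted p = 4.74e-11) and Ccnb1 from 0.0203 to 86.5 CPM (ratio 3790, 95% counting interval 680 to 149744). Of 40 replication genes 36 rose and 1 fell, 37 and 1 adjusted over the list alone, among them Mcm5 (38.9-fold). Together the 40 had a median of 2.51 (adjusted p = 3.27e-39, and adjusted p = 0.00609 with an estimated correlation). Of 22 DNA repair genes 17 rose and none fell, 17 adjusted over the list alone. Together the 22 had a median of 2.76 (adjusted p = 1.14e-12, and adjusted p = 0.00674 with an estimated correlation). Ccnd1 rose 11.1-fold (log2 fold change 3.47, SE 0.23, adjusted p = 1.94e-09), Lmnb1 3.07-fold (1.62, SE 0.24, adjusted p = 2.91e-05) and Cdkn1a 8.57-fold (3.10, SE 0.64, adjusted p = 0.00491). The Cdkn1a responses of the arms did not differ past the interaction test (1.54, SE 0.84, adjusted p = 0.527). Cyp8b1 fell 83.3-fold from 474 ± 71.3 to 5.64 ± 1.48 CPM (log2 fold change -6.38, SE 0.50, adjusted p = 8.03e-06), and the citrate and succinate transporter Slc13a2 fell 32.5-fold (adjusted p = 1.03e-07). In all, 4731 genes passed, 2398 higher and 2333 lower, 38.6% of those tested. Across the 12257 genes, which are not independent of one another, the responses of the arms correlated with Pearson r = 0.822 and Spearman rho = 0.717, and the arms share no library. Of 3000 genes past the test in both, 1540 rose in both (413 by independent lists), 1443 fell in both (382 by independent lists) and 17 went opposite ways.

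Among 28 acute phase genes in P16 mice after hepatectomy 18 rose and 1 fell, 21 and 2 adjusted over the list alone. Together the 28 had a median of 1.17 (adjusted p = 0.00116, and adjusted p = 0.671 with an estimated correlation). In GFP mice 1 of them rose and 9 fell, 1 and 9 adjusted over the list alone (list median -0.28, adjusted p = 0.126). Their members Lcn2 (log2 fold change 8.12, SE 1.59, adjusted p = 0.00404) and Saa2 (8.46, SE 1.94, adjusted p = 0.00899) rose, Saa2 within a family of close copies. Coagulation genes were not called (13 of 20 fell and 4 rose, 13 and 4 adjusted over the list alone, median -0.39, adjusted p = 0.0861). Of 80 ribosomal protein genes 61 rose, 70 adjusted over the list alone, and none fell. Together the 80 had a median of 0.57 (adjusted p = 2.77e-08, and adjusted p = 0.671 with an estimated correlation). In GFP mice 44 rose, 50 adjusted over the list alone, and none fell, with a list median of 0.40 (adjusted p = 5.49e-05, and adjusted p = 0.769 with an estimated correlation). Of 12 male-biased genes 11 fell, 11 adjusted over the list alone, including Hsd3b5 (14.1-fold) and Mup1 (11.4-fold). Together the 12 had a median of -2.26 (adjusted p = 9.49e-14, and adjusted p = 0.0492 with an estimated correlation). Of 21 bile acid genes 14 fell and 1 rose, 15 and 1 adjusted over the list alone, including Cyp7b1 (log2 fold change -2.22). Together the 21 had a median of -0.999 (adjusted p = 2.32e-07, and adjusted p = 0.121 with an estimated correlation). Of 29 fatty acid oxidation genes 17 fell and 1 rose, 17 and 1 adjusted over the list alone, including the acyl-CoA synthetase Acsl1 (3.78-fold). Together the 29 had a median of -0.55 (adjusted p = 2.81e-05, and adjusted p = 0.119 with an estimated correlation). Of the 12 mitochondrially encoded transcripts 7 fell, 9 adjusted over the list alone. Together the 12 had a median of -0.77 (adjusted p = 0.0204, and adjusted p = 0.671 with an estimated correlation). That call was lost without P16 replicate 1 at 0 h or at 48 h (highest adjusted p = 0.0735), and the median was -1.16 without P16 replicate 2 at 48 h. The mitochondrial share of reads was 12.9 to 22.6% at 0 h and 9.17 to 14.3% at 48 h.

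Further lists were called after hepatectomy in both arms with the preset correlation. Of 16 periportal genes 10 fell and 1 rose in GFP mice, 10 and 1 adjusted over the list alone (median -0.82, adjusted p = 8.02e-05, and adjusted p = 0.219 with an estimated correlation). In P16 mice 5 of them fell and 1 rose, 5 and 1 adjusted over the list alone (median -0.41, adjusted p = 0.0208, and adjusted p = 0.599 with an estimated correlation), a call lost without P16 replicate 3 at 48 h (adjusted p = 0.0640, the highest over the alternatives). Of 20 hepatocyte identity genes 9 fell and 1 rose in each arm, 9 and 2 in GFP and 9 and 1 in P16 mice adjusted over the list alone. Their medians were -0.45 (adjusted p = 0.00599, and adjusted p = 0.344 with an estimated correlation) and -0.47 (adjusted p = 0.0116, and adjusted p = 0.586 with an estimated correlation). Of 15 genes of the G1 phase and its inhibitors 7 rose and none fell in GFP mice, 9 higher and 1 lower adjusted over the list alone (median 0.50, or 0.48 with bounds, adjusted p = 5.36e-04, and adjusted p = 0.0553 with an estimated correlation). In P16 mice 6 rose and 2 fell, 6 and 2 adjusted over the list alone (median 0.38, adjusted p = 0.00461, and adjusted p = 0.102 with an estimated correlation). Ccnd1, a member, rose in both arms. In P16 mice 12 of 18 glucose genes fell, 12 adjusted over the list alone (median -0.93, adjusted p = 2.20e-04, and adjusted p = 0.102 with an estimated correlation). Of 26 urea cycle and amino acid genes 16 fell and 1 rose there, 16 and 1 adjusted over the list alone (median -0.66, adjusted p = 2.81e-05, and adjusted p = 0.586 with an estimated correlation). Of 19 p53 targets 11 rose and 2 fell, 11 and 2 adjusted over the list alone (median 0.999, adjusted p = 0.00324, and adjusted p = 0.215 with an estimated correlation). Of 73 oxidative phosphorylation genes 22 fell and 2 rose, 20 and 2 adjusted over the list alone (median -0.29, adjusted p = 0.00485, and adjusted p = 0.777 with an estimated correlation), a call lost without P16 replicate 2 at 0 h (adjusted p = 0.0511, the highest over the alternatives).

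**Figure D3:**
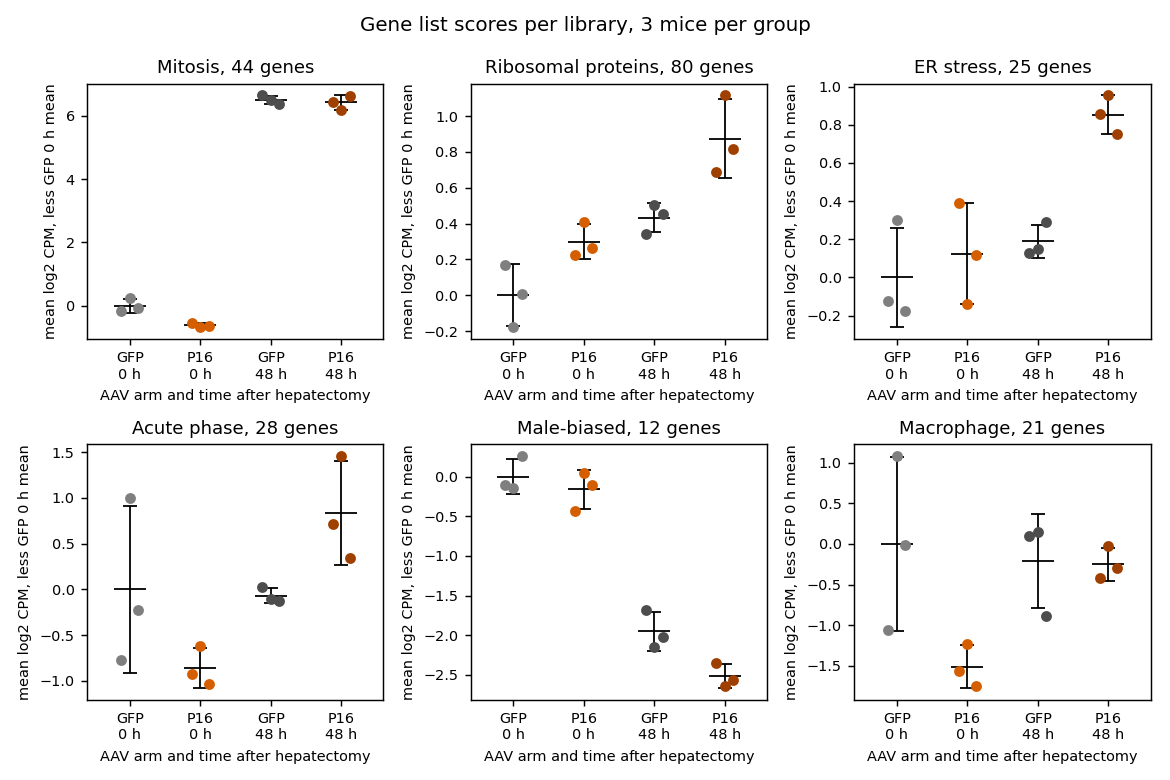
Mean log2 CPM of the genes of 6 lists less the mean of GFP mice at 0 h (vertical axis of each panel, log2 units) in GFP and P16 mice at 0 h and 48 h (horizontal axis), with each point a mouse and bars for the mean and SD of 3. Mitosis genes rise in both arms, endoplasmic reticulum stress genes at 48 h score 0.130 to 0.289 in GFP and 0.750 to 0.954 in P16 mice, and macrophage markers at 0 h score 1.08 in GFP replicate 2.

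The interaction asks whether the response to hepatectomy differed between the arms, which equals asking whether the P16 effect differed between the times. Erbb3 (chromosome 10, 128567523 to 128589652), a receptor of the epidermal growth factor receptor family, was 91.2 ± 8.38 CPM in GFP and 144 ± 14.9 CPM in P16 mice at 0 h, and 91.4 ± 4.06 against 53.5 ± 4.54 CPM at 48 h (interaction -1.43, SE 0.17, adjusted p = 0.00131). It was the single gene past the test between the arms at both times, in opposite directions. Lists this short share few genes by chance: independent lists would give 0.186 genes higher at both times and 0.125 lower at both. The number expected in opposite directions, the case of Erbb3, was not computed. Tcp11l2 (interaction -1.85, SE 0.28, adjusted p = 0.0131) and the apoptosis initiator Casp9 (-1.41, SE 0.24, adjusted p = 0.0351) were lower in P16 mice at 48 h relative to 0 h. Grn, the progranulin gene, went the other way, at 163 against 90.7 CPM at 0 h and 141 against 186 CPM at 48 h (1.24, SE 0.21, adjusted p = 0.0351). So did the complement gene C3, at 6668 against 4536 CPM and 5649 against 10146 CPM (1.40, SE 0.26, adjusted p = 0.0471). In all, 12 genes passed, 4 higher and 8 lower, against 1451 at an unadjusted p under 0.05 (227 by DESeq2 and 29 by limma-voom). Fold changes of P16 over GFP at 0 h and at 48 h correlated weakly across genes (Pearson r = 0.103, Spearman rho = 0.142). Acute phase genes had the lowest list p: 1 of 28 passed, 22 were higher adjusted over the list alone, and the median was 1.52 (adjusted p = 1.39e-25, and adjusted p = 0.267 with an estimated correlation). Macrophage markers moved with them, with a slightly larger median of 1.57 (adjusted p = 3.08e-08, and adjusted p = 0.548 with an estimated correlation). Of 21 markers 0 passed the edgeR test over all genes, 9 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom, and 1 was higher adjusted over the list alone. Without GFP replicate 2 at 0 h and P16 replicate 2 at 48 h the medians were 1.00 and 0.56. Lmnb1 (-1.32, SE 0.34, adjusted p = 0.119) and Mki67 (2.25, SE 0.56, adjusted p = 0.103) did not pass. Nor did Cdkn2a (-3.95, SE 5.35, adjusted p = 0.843), Glb1 (0.32, SE 0.29, adjusted p = 0.723) or Hmgb1 (-0.25, SE 0.17, adjusted p = 0.606). The count was 76, 19 and 8 without GFP replicate 1, 2 and 3 at 0 h, 30 without P16 replicate 2 at 0 h, and 2 without GFP replicate 1 or 3 at 48 h. It was 4 and 35 without P16 replicate 2 and 3 at 48 h. Erbb3 kept its call under all 19 alternatives. Tcp11l2 lost it without GFP replicate 1 or 3 at 48 h (highest adjusted p = 0.0639), and Casp9, Grn and C3 lost it without those libraries or P16 replicate 2 at 48 h (up to 0.111, 0.113 and 0.123). Grn and C3 lost it without P16 replicate 1 or 3 at 0 h as well, and C3 also without GFP replicate 3 at 0 h or GFP replicate 2 at 48 h.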

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

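The tests of technical explanations in this part were all chosen after the result was seen, whereas the counts over other splits of the samples were planned.

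What drew attention to 12 genes was a response to hepatectomy that differed between the arms in the interaction test. The interaction log2 fold changes were -1.43 for Erbb3, 4.72 for Gm379, -1.85 for Tcp11l2, -1.41 for Casp9, 1.24 for Grn, -1.51 for Mup1, 1.23 for Zdhhc20, -1.49 for Mup7, -0.995 for Atxn2, -1.04 for Bcar1, 1.40 for C3 and -1.05 for Ugt3a1. Gm379, a gene model without a name, went from 3.00 ± 1.43 CPM in GFP and 0.300 ± 0.275 CPM in P16 mice at 0 h to 2.78 ± 0.766 and 7.80 ± 2.98 CPM at 48 h. The palmitoyltransferase gene Zdhhc20 was 16.3 ± 1.49 and 11.1 ± 1.05 CPM at 0 h and 10.5 ± 0.834 and 16.8 ± 1.21 CPM at 48 h. Mup7 was 3223 ± 517 and 4182 ± 1129 CPM at 0 h and 1186 ± 213 and 546 ± 17.3 CPM at 48 h. Of 100 splits of the libraries within each time, drawn from 200 possible, 2 gave at least 12 genes, the real one included. Swapping the arms within each time also breaks up a P16 effect shared by both times. This share, though under 0.05, therefore does not exclude chance for the interaction. The highest of the other splits gave 32, more than the real one, and what set its samples apart was not tested.

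The same test drew attention to 14 gene lists, with median interaction log2 fold changes of 0.52 for mitosis, 0.64 for the senescence-associated secretory phenotype, 0.34 for coagulation, 1.52 for acute phase, -0.25 for lipogenesis, -0.41 for bile acid, 0.42 for periportal, -0.37 for male-biased, 0.69 for endoplasmic reticulum stress, 0.20 for ribosomal protein, 0.86 for mitochondrially encoded, -0.54 for histone, 1.57 for macrophage and 0.67 for endothelial genes. With an estimated correlation 0 of 36 lists were called, and the lowest adjusted p was 0.267. Chance is not excluded for the number of lists: 16 of 100 splits gave at least 14, and the highest of the other splits gave 20. The ribosomal protein list lost its call without GFP replicate 1 at either time and without P16 replicate 2 at 48 h (adjusted p = 0.482 and a median of 0.07), and the endothelial list without GFP replicate 2 at 0 h. With that library and P16 replicate 2 at 48 h both left out, calls were lost by the endothelial (median 0.08, adjusted p = 0.480), lipogenesis (-0.03, adjusted p = 0.824), bile acid (adjusted p = 0.0820) and male-biased lists (-0.20, adjusted p = 0.0572), each the highest over its alternatives. The histone list lost its call with no filter, at a median of -0.09 (adjusted p = 0.420, its highest). The mitosis list lost its call without GFP replicate 2 or P16 replicate 2 or 3 at 0 h or P16 replicate 3 at 48 h (adjusted p up to 0.0989), the bile acid list without GFP replicate 2 at 0 h (its median was -0.26 without GFP replicate 1 at 48 h), and the male-biased list without GFP replicate 1 at either time or P16 replicate 2 at 0 h. The periportal list lost its call without GFP replicate 1 or P16 replicate 3 at 0 h or P16 replicate 1 at 48 h (adjusted p up to 0.168, with a median of 0.23), the histone list without GFP replicate 1 or P16 replicate 2 at 0 h, and the lipogenesis list without GFP replicate 2 or P16 replicate 3 at 0 h or GFP replicate 2 or 3 or P16 replicate 3 at 48 h. Medians were larger without GFP replicate 1 at 0 h for lipogenesis (-0.44) and without P16 replicate 1 at 0 h for male-biased genes (-0.56).

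Between the arms and between the times, 3 against 3 mice make 10 splits, which are too few for a share under 0.05. For genes, 1 of 10 splits, the real one, reached the real count in each of 4 comparisons: 27 at 0 h (highest other 3), 280 at 48 h (highest other 0), 4117 after hepatectomy in GFP mice (highest other 0) and 4731 in P16 mice (highest other 0). For lists, 8 of 10 splits gave at least the real 7 at 0 h (highest other 17) and 8 of 10 at least the real 9 at 48 h (highest other 20). After hepatectomy 4 of 10 gave at least the real 17 in GFP mice (highest other 20) and in P16 mice (highest other 22).

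The ribosomal protein, endoplasmic reticulum stress and acute phase lists were called higher in P16 mice at 48 h with the preset correlation and not with an estimated one (adjusted p = 0.335), which was set against a trend with gene length or GC content and against P16 replicate 2, the library that stood apart. After offsets for length and GC the medians were 0.33 for ribosomal protein genes, 0.70 for stress genes and 1.00 for acute phase genes, from 0.46, 0.64 and 1.05. The scores then differed by 0.334 (SE 0.103), 0.656 (SE 0.0751) and 0.867 (SE 0.321), which argues against such a trend as the whole cause. Without P16 replicate 2 the medians were 0.33, 0.58 and 0.65, and the scores differed by 0.320 (SE 0.0793), 0.615 (SE 0.0730) and 0.597 (SE 0.188). These values argue against that library as the whole cause, though it carried part of the acute phase and ribosomal difference. All 3 lists kept their calls in both fits, but this adds little. At 48 h 8 of 10 splits gave at least the real 9 lists. An effect of P16 on hepatocytes under regenerative load may account for the pattern, and so could inflammation or day of collection differing between the mice, since the labels give no day. The lists are therefore a hypothesis to follow through single genes such as Sdf2l1.

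The macrophage and acute phase lists were called lower in P16 mice at 0 h with the preset correlation. With an estimated one 0 lists were called (lowest adjusted p = 0.706). Both patterns were set against GFP replicate 2 standing apart, and the macrophage one against fewer cells of all other types in the P16 preparations. Without GFP replicate 2 the macrophage median was -0.72 against -1.67 with all libraries and still called with the preset correlation. The acute phase median was -0.14, from -0.50, so how much of either pattern rests on that mouse stays open. With GFP replicate 1 left out instead, the medians were -2.04 for macrophage and -0.66 for acute phase genes. The macrophage score changed by -1.28 (SE 0.496) more than the mean of endothelial, stellate and cholangiocyte scores, and by -0.861 (SE 0.379) without GFP replicate 2. With at most 3 mice per group, these values do not decide whether a purer P16 preparation lowered all other cell types alike. Fewer macrophages, or less active ones, in P16 livers may account for the macrophage pattern. So may inflammation in GFP replicate 2 or a purer P16 preparation. The count table has no measure of macrophage number that is independent of these markers, and the stated purity of the preparations was at least 95%.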

How the results depend on the processing

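Length and GC offsets and the fit without GFP replicate 2 at 0 h and P16 replicate 2 at 48 h (2 libraries left out) were chosen after the data were seen. Genes past the test at 0 h (27) became 160 with no filter, 214 with DESeq2, 4 at an adjusted p under 0.01, 9 with the 6 libraries compared alone, and 5 to 148 with each library left out. At 48 h, 280 became 538 with no filter, 145 with 2 libraries left out, 707 with DESeq2, 972 with limma-voom, 20 at an adjusted p under 0.01, 76 with a 2-fold change required, 752 with 6 libraries, and 10 to 404 with each library left out. After hepatectomy, 4117 genes in GFP mice became 2604 at an adjusted p under 0.01, 1753 at 2-fold and 3011 to 4067 with each library left out, and 4731 in P16 mice became 3151, 2096 and 3885 to 4246. The interaction (12) gave 6 with upper-quartile scaling (3 higher and 3 lower, against 4 and 8), 173 with no filter, 27 with the offsets, 28 with 2 libraries left out (19 higher), 227 with DESeq2, 29 with limma-voom, 1 at an adjusted p under 0.01, and 2 to 76 with each library left out. Lists called were 7 at 0 h (11 with 2 libraries left out, 7 to 13 with each library left out), 9 at 48 h (8 to 12), 17 in GFP mice (17 to 20), 17 in P16 mice (16 to 19) and 14 in the interaction (10 to 17). With an estimated correlation they were 0, 0, 3, 4 and 0, and fry, at 0 in both comparisons of the arms and the interaction, found members moving in either direction in 11 lists at 0 h and 18 at 48 h. The correlation of the hepatectomy responses (0.822) was 0.412 with no filter and 0.749 to 0.807 with each library left out, and that of the P16 effects (0.103) was 0.0180 and 0.0680 to 0.115. No filter adds genes of few counts, and leaving libraries out removes replicates; for the other settings the cause was not tested. The replicate numbers share only a number: 0 of 18 same-numbered pairs correlated over 0.1 (mean 0.00775) and 5 of 12 libraries were closest to their own number. With the replicate block the counts were 20 at 0 h, 150 at 48 h (138 of them among the 280) and 44 in the interaction. No named gene past the test changed sign. Calls held under all 13 alternatives run for single genes (19 in the interaction) for 1 of 13 genes named as changed at 0 h, 3 of 42 at 48 h, 111 of 135 and 105 of 128 after hepatectomy, and 1 of 8 in the interaction. Of named genes that did not pass, 22 of 72 at 0 h and 29 of 54 at 48 h passed under at least 1 alternative. Depth limits genes near the floor of 0.0961 to 0.238 CPM.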

Other observations

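The test of the clock genes below was chosen after the result was seen.

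The list of antioxidant and detoxification genes that NRF2 controls was called higher after hepatectomy in both arms with the preset correlation and not with an estimated one. Of 18 tested, 10 rose and none fell in GFP mice (10 higher and 1 lower adjusted over the list alone, median 0.67, adjusted p = 5.97e-04, and adjusted p = 0.340 with an estimated correlation), and the numbers were the same in P16 mice (median 0.91, adjusted p = 0.00750, and adjusted p = 0.605 with an estimated correlation). Gstm3, a glutathione transferase, rose from 66.1 ± 41.5 to 2346 ± 235 CPM in GFP mice (35.6-fold, adjusted p = 2.51e-04) and from 74.6 ± 18.5 to 2114 ± 935 CPM in P16 mice (28.4-fold, adjusted p = 2.97e-04). Gsta1, another, rose 26.2-fold (adjusted p = 7.24e-04) and 32.2-fold (adjusted p = 4.74e-04), and the quinone reductase gene Nqo1 rose 7.32-fold (adjusted p = 3.85e-06) and 4.54-fold (adjusted p = 3.76e-05). Glutathione transferase genes have close copies, so Gstm3 and Gsta1 are uncertain. In the interaction the list was not called (median -0.18, adjusted p = 0.478).

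The immediate early list, whose genes also respond to cell isolation, was called higher in P16 mice at 48 h. Of 25 tested, 0 passed in edgeR over all genes, 5 at an unadjusted p under 0.05, 3 in DESeq2 and 8 in limma-voom, and 3 were higher adjusted over the list alone (median 0.63, adjusted p = 5.39e-05, and adjusted p = 0.335 with an estimated correlation). Junb had a log2 fold change of 1.53 (adjusted p = 0.0692) and Fos of 1.87 (adjusted p = 0.0838). The interaction of this list did not pass (median 0.17, adjusted p = 0.441).

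A list of 11 clock genes that peak with Dbp, chosen after values were seen and adjusted over 2 clock lists, was called higher in P16 mice at 0 h with the preset correlation (median 0.51, adjusted p = 0.0101) and not with an estimated one (p = 0.225). Dbp had a log2 fold change of 4.20 (SE 1.05, adjusted p = 0.176) and Nr1d1 of 1.93 (SE 0.36, adjusted p = 0.0839, the lowest of the list), while Per1 (-1.66), Usp2 (-0.88), Ciart (-0.81) and Hlf (-0.10) lay the other way. Of the 11 genes 7 had a positive log2 fold change, and 5 genes that peak with Arntl had a median of 0.01 (adjusted p = 0.216). At 48 h neither list was called (medians -0.19, adjusted p = 0.582, and 0.14, adjusted p = 0.135), and Nfil3, of the Arntl group, was the single clock gene past the edgeR test (log2 fold change 1.08, SE 0.24, adjusted p = 0.0401), a call not run under the alternatives. A candidate explanation is that the P16 and GFP mice were taken, or had fed, at different times of day. That would move both phases in opposite directions, and the score of the Dbp phase less that of the Arntl phase was 0.99 higher in P16 mice (SE 0.733), too variable between mice to decide. Times of collection would settle it and are not given in the sources used here. The same score also separated the times without overlap. In GFP mice it was at most 0.825 at 0 h and at least 2.56 at 48 h. In P16 mice it was at most 1.80 at 0 h and at least 2.58 at 48 h. These values do not separate an effect of surgery from a difference in time of day or feeding.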
